A study of Rattus norvegicus with 8 samples.

How the data were processed

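Total RNA was isolated with TRI Reagent from diaphragms snap-frozen at collection, and libraries were made with a SMARTer ultra-low-input kit, which copies RNA from its poly(A) tail without keeping strand, and a KAPA Hyper kit, per the labels' protocols. They were sequenced on an Illumina NextSeq 500. The deposited table holds raw whole read counts per gene symbol, 1 column per animal, and per the submitters' processing notes the tools were bcl2fastq, STAR 2.5.0a, TopHat2 or TopHat and Cufflinks with genome build rn5. The program that counted the reads, the annotation and the handling of reads that map to several places are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and near-identical copies such as the globin genes may share or lose reads.

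The table held 17055 rows, of which 3121 were 0 in every library. Of the symbols, 25 had been turned into dates by a spreadsheet, with 0.109% of the counts. They stayed in the library sizes and tests but are not named. Against a list of RefSeq genes of the GRCr8 assembly, 14175 rows matched a current symbol and 2369 an older synonym, and 511 did not match. Because that assembly differs from rn5, it was used for names only and no coordinates are given. Every column belonged to 1 of the 8 labelled animals.

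Groups were taken from the labels, which number the animals separately and give no batch and no pairing. The animal numbers fall in 2 ranges, one with MI replicates 1 and 2 and Sham replicate 5 and the other with the remaining 5 animals, and a term for the range was 1 of the alternatives. Pairs of libraries within a group differed far beyond sampling noise, with a chi-square per degree of freedom of 12.1 to 44.3 over genes with at least 10 counts in the pair, so each library counted as 1 replicate.

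Gene tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, and the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 10522 genes that passed the filter and a threshold of 0.05. The common biological coefficient of variation was 17.3%. The median SE of a log2 fold change was 0.145 and the median fold change of all genes was -0.0070 on the log2 scale. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 33 lists with at least 5 tested members. Each list was also tested with an estimated correlation, with fry, which asks whether members move on balance one way without reference to other genes, and with an exact two-sided permutation test of its mean log2 CPM (prior count 2) over the 70 arrangements of 4 and 4 animals, whose smallest p is 0.0286. Principal components were computed on log2 CPM of the 500 most variable genes.

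The tests, the 34 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Under that rule the text names, in each direction, up to 12 genes past the threshold with a mean of at least 1 CPM and no overlap between groups, or otherwise the 6 such genes with the smallest p. It also names up to 4 members of each list with the smallest p, and Myh7, Myh2, Myh1, Myh4, Fbxo32, Trim63, Col1a1, Col3a1, Cybb, Ppargc1a and Atp2a1 whatever their result. For some lists only the first 2 are named, a choice made after the values were seen. Some list members that the rule picks are not reported here. Genes outside it appear in the closing section and were chosen after their values were seen.

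Alternatives were size factors by the RLE method, library totals alone, no filter on low counts, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, the test without robust estimation, a threshold of 0.1, an added fold threshold of 1 on the log2 scale, the animal number range or 1 surrogate variable (sva 3.50.0) as a term, and each library left out in turn. For the mean levels of the lists, a prior count of 0.5 was a further alternative. Counts thinned to the total of the smallest library were added after seeing the data.

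The procedure was tested on simulated data drawn from the means and library sizes of this comparison, with 200 of 10522 genes changed. Of genes passing the filter, edgeR recovered 32.8% of those changed 1.5-fold, 79.1% of those changed 2-fold and 97% of those changed 3-fold, with 8 false calls, and DESeq2 34.3%, 82.1% and 95.5% with 19 false calls. With no gene changed edgeR called 0. A simulated list raised throughout reached an adjusted p of 1.15e-15 with camera and 0.00229 with an estimated correlation, and 0 of 30 unchanged lists were called. The simulated genes varied independently of one another, with the dispersion typical of their expression level rather than each gene's own. Recovery at an adjusted p also depends on the 200 changed genes, and is lower where fewer genes change.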

Results

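Diaphragm, the main muscle of inspiration, was profiled by RNA sequencing in 8 Sprague-Dawley rats 16 weeks after surgery. In 4 animals a myocardial infarction (MI) had been caused by tying off a coronary artery (the left anterior descending), and 4 Sham animals had the same operation without the tie. Each animal gave 1 library. The MI libraries, replicates 1 to 4, held 15001575, 15944048, 12405307 and 8566143 counts, and the Sham libraries, replicates 5 to 8, held 13741348, 16284264, 24967251 and 7941402. Between 12317 and 13055 genes had a count in a library, and the 10 most abundant genes took at most 19.2% of the counts of a library. A floor of 3 counts corresponded to 0.120 to 0.378 counts per 1000000 (CPM) across libraries, which covers counting error only. The comparison of MI with Sham asks which transcripts differ in the diaphragm during the remodelling that follows an infarction.

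Among genes whose 4 MI values all lay below the 4 Sham values, the smallest p belonged to Trim63, the muscle ubiquitin ligase also called MuRF1, at 240.0 ± 8.18 CPM in MI against 330.1 ± 19.1 in Sham (SD, n = 4 each), a log2 fold change of -0.46 ± 0.07 (SE). Figf, the lymphatic growth factor also called Vegfd, was at 1.76 ± 0.867 against 6.48 ± 0.991 CPM, a log2 fold change of -1.91 ± 0.30. Its receptor Flt4, a marker of lymphatic endothelium, was at 3.82 ± 0.537 against 9.31 ± 2.48 CPM (-1.26 ± 0.21). Zbtb16, a transcription factor that responds to glucocorticoids, was at 34.0 ± 8.33 against 69.3 ± 10.9 CPM (-1.03 ± 0.18). Among genes whose MI values all lay above Sham, Sh3bgrl was at 119.8 ± 14.4 against 84.6 ± 4.60 CPM (0.50 ± 0.09), and the alpha-globin gene Hba2 at 89.1 ± 24.8 against 42.4 ± 11.4 CPM (1.08 ± 0.24).

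None of these genes passed the edgeR quasi-likelihood test, in which 0 of 10522 genes were higher and 0 lower at an adjusted p under 0.05. The smallest adjusted p was 0.286, shared by Trim63, Figf and Flt4, and it was 0.518 for Zbtb16 and Sh3bgrl and 0.601 for Hba2. At an unadjusted p under 0.05 edgeR gave 386 higher and 470 lower genes, 856 in all, where chance alone would give 526.1. The groups did not overlap for 220 genes with higher and 259 with lower MI values, 4.55% of the genes tested against 2.86% by chance on average. This share was not counted over other divisions. DESeq2 on the same counts called 9 genes higher and 5 lower, including Trim63 and Figf (both adjusted p = 1.36e-05), Flt4, Zbtb16, Sh3bgrl, Cul5, Casp12 and Hba2, while limma-voom called 0 in either direction. Without Sham replicate 7 the number at an unadjusted edgeR p under 0.05 was 514.

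The remaining genes with the smallest p in each direction had smaller or less abundant differences, each at an adjusted edgeR p of 0.601. Itga11, a collagen-binding integrin subunit, had a log2 fold change of -0.66 ± 0.14, and Sema3f, a secreted semaphorin, -0.68 ± 0.15. On the higher side, Cul5, a scaffold of ubiquitin ligases, had 0.39 ± 0.08, Casp12, a caspase of the endoplasmic reticulum, 0.83 ± 0.18, and the zinc finger gene Zfp317 0.41 ± 0.09. Gria4, a glutamate receptor subunit, was at 1.48 ± 0.267 against 0.553 ± 0.256 CPM (1.55 ± 0.37), close to the counting floor of the smallest libraries. All 12 of these genes kept their sign in each alternative in which they were tested. Because they were picked for no overlap between the groups, this was largely fixed beforehand and gives no separate support.

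**Figure D1:**
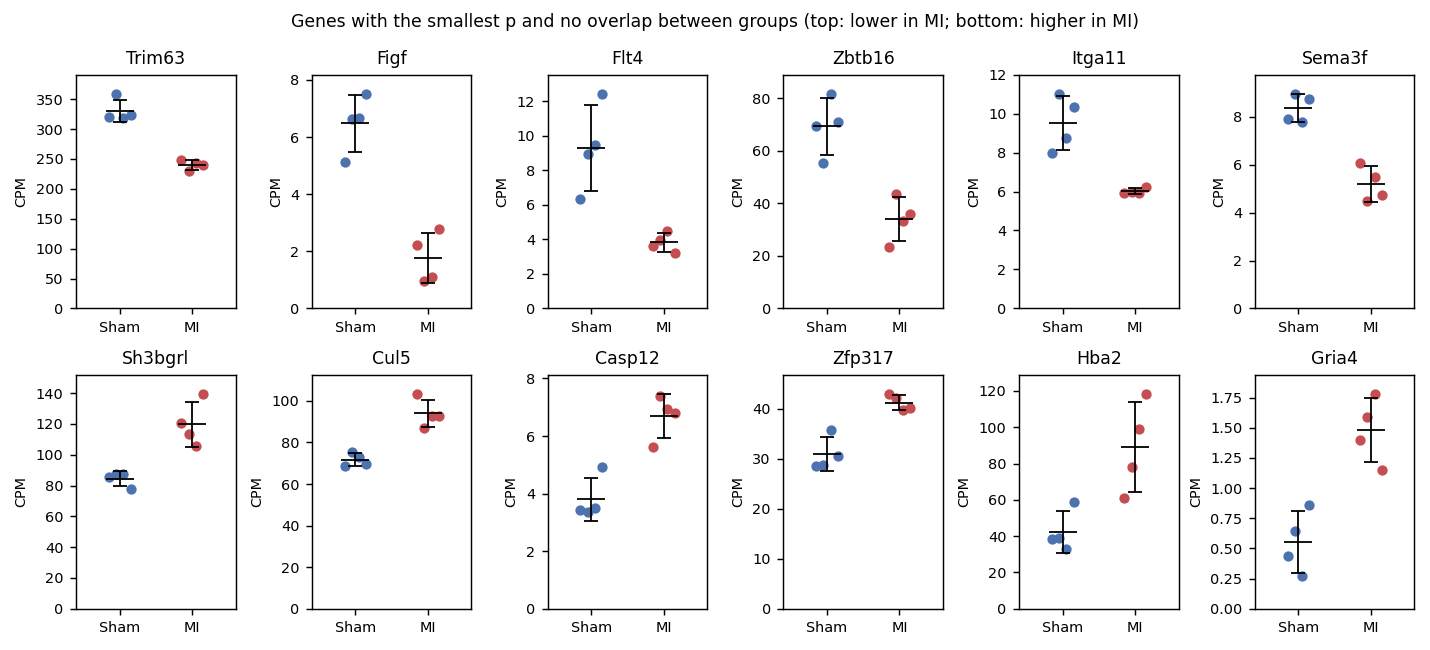
CPM (vertical axes) of the 12 genes with the smallest p and no overlap between groups, 1 point per library, with a line and bars for the mean ± SD of the 4 Sham and the 4 MI animals. The 4 MI values of Trim63 average 240.0 and the 4 Sham values 330.1, and no gene shown passed the adjusted threshold in edgeR.

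Red blood cell genes had the largest median difference of the 34 gene lists. All 8 tested members were higher in MI, with a median log2 fold change of 1.10, and the mean level of the list was 4.84 ± 0.48 log2 CPM in MI against 3.64 ± 0.08 in Sham (SD, n = 4 each). Hba2, Hba1 (219.0 against 102.2 CPM) and Hbb-b1 (20.2 against 9.42 CPM) encode globin chains, and Alas2, the erythroid enzyme that starts haem synthesis, had 23.5 CPM in MI and a log2 fold change of 1.10 ± 0.26. In edgeR, members past the threshold numbered 7 when adjusted over the list alone and 0 over all genes. DESeq2 called 5 members over all genes, among them Hba1 (adjusted p = 0.00168), Hba2 (0.00256), Hbb-b1 (0.0144) and Alas2 (0.01995). The globin genes are near-identical copies among which the counting could have divided reads, so the value of each copy is uncertain. The camera test with its preset correlation placed the list higher in MI (adjusted p = 4.5e-20), which was lost at adjusted p = 0.151 with an estimated correlation and at 0.255 with fry.

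Nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase subunits, lay slightly above Sham in MI. Of 70 tested members, 65 had a log2 fold change above 0 and 29 an unadjusted p under 0.05, with a median of 0.17. Cox5a, a subunit of cytochrome c oxidase, was at 955 against 772 CPM (log2 fold change 0.31 ± 0.08), and Ndufb5, Ndufs5 and Atp5j had log2 fold changes of 0.24, 0.30 and 0.25. No member passed in edgeR over all genes or when adjusted over the list alone, and DESeq2 called 1 over all genes, Cox5a (adjusted p = 0.0463). Camera gave an adjusted p of 2.21e-16, and the call was lost at adjusted p = 0.712 with an estimated correlation and at 0.278 with fry. The mean level of this list, like that of the red blood cell list above, was higher in each of the 4 MI libraries than in any Sham library. For oxidative phosphorylation this was a near tie, with MI replicate 2 at 8.770 log2 CPM and Sham replicate 5 at 8.767. For red blood cell genes the lowest MI library was at 4.21 and the highest Sham library at 3.75.

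Genes of the protein-making and protein-degrading machinery showed differences of similar small size. Cytosolic ribosomal proteins had 48 of 51 members above 0 and a median log2 fold change of 0.13, with Rps13 at 0.27 ± 0.10, Rps20 at 0.25 and Rpl27 at 0.25 (0.15 without MI replicate 1). Proteasome subunits had 22 of 31 members above 0 and a median of 0.084, led by Psma2 (0.26 ± 0.08), Psmb1 (0.22), Psmb4 (0.25) and Psmc6 (0.20). In MI replicate 2 the mean ribosomal protein level, 5.54 log2 CPM, lay below all 4 Sham libraries, and the mean proteasome level, 7.61, below Sham replicates 5 and 6. No member of either list passed in edgeR over all genes or when adjusted over the list alone. Camera called both lists higher, at adjusted p = 1.19e-06 for ribosomal proteins and 0.000847 for the proteasome. With an estimated correlation both calls were lost, at adjusted p = 0.966 for each, and with fry at 0.667 and 0.578.

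Schwann cell and nerve markers were the last group that camera called higher (adjusted p = 0.0267), with 6 of 10 members above 0 and a median log2 fold change of 0.32. In edgeR, members past the threshold numbered 1 when adjusted over the list alone and 0 over all genes. Pmp22, Pllp and Mbp, all myelin genes, had log2 fold changes of 0.27, 0.57 and 0.60, the last 0.28 without MI replicate 2. The call was lost at adjusted p = 0.327 with an estimated correlation and 0.329 with fry. It was also lost without MI replicate 2 (adjusted p = 0.0529), MI replicate 3 (0.0551) or Sham replicate 5 (0.0924).

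**Figure D2:**
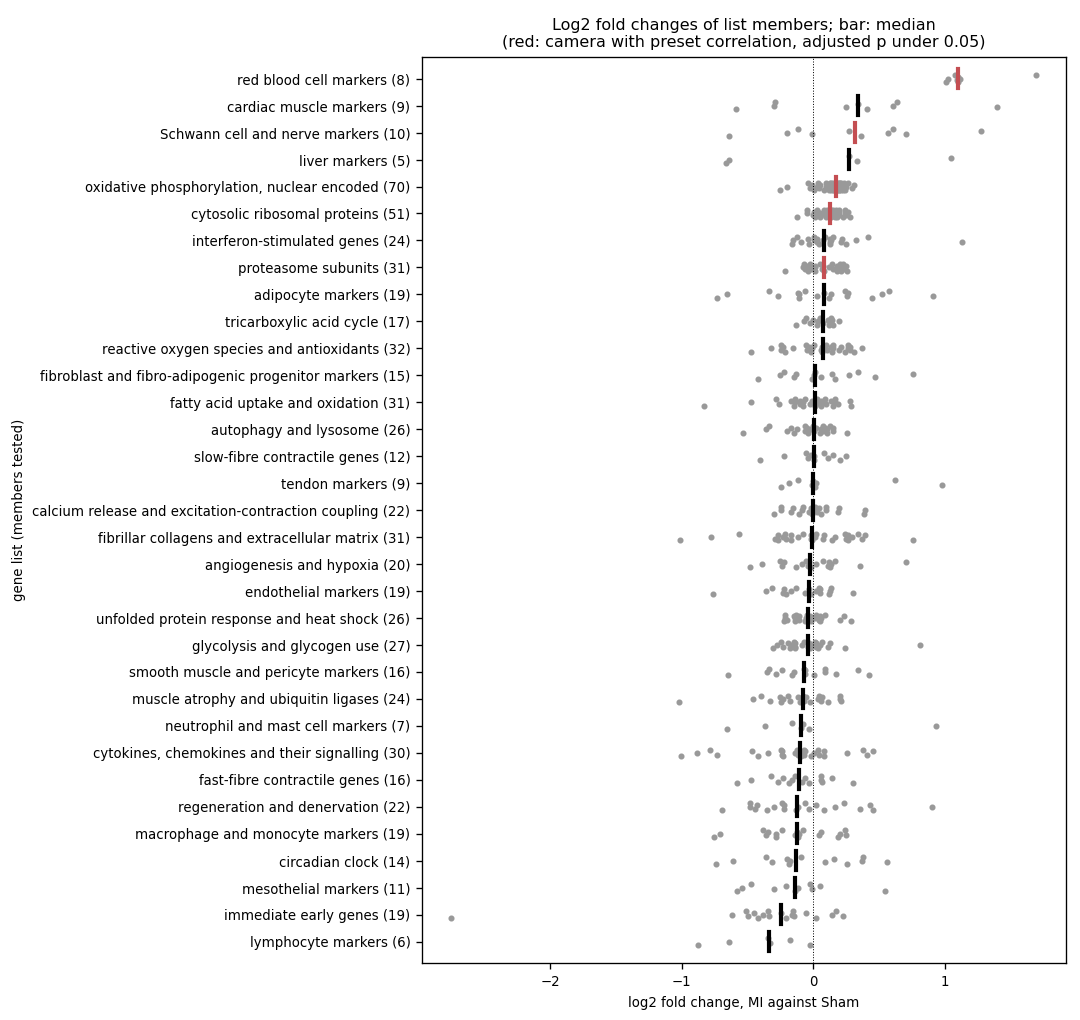
Log2 fold change, MI against Sham, of the members of each of the 33 tested gene lists (grey points, horizontal axis), with a bar at the list's median that is red where camera with its preset correlation gave an adjusted p under 0.05. The 5 red bars are the red blood cell (1.10), Schwann cell (0.32), oxidative phosphorylation (0.17), ribosomal protein (0.13) and proteasome (0.084) lists, and 0 lists passed with an estimated correlation.

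Contractile genes of slow and fast fibres gave no call. Here and below, a log2 fold change in brackets with a library left out is the one nearest to 0, given where the value shrank by over 1.5 times. The slow-fibre list had a median log2 fold change of 0.0044 over 12 tested members (camera adjusted p = 0.797), with Myl2, a slow myosin light chain, at 0.21 ± 0.09 (0.14 without Sham replicate 7). Myh7, the slow myosin heavy chain, was at 3514 ± 1016 CPM in MI against 4645 ± 818 in Sham (SD, n = 4 each), a log2 fold change of -0.40 ± 0.21 (edgeR adjusted p = 0.639; -0.25 without MI replicate 1). The fast-fibre list had 11 of 16 members below 0 and a median of -0.11 (camera adjusted p = 0.225), with Mylk2, the skeletal myosin light chain kinase, at -0.58 ± 0.25 (-0.32 without Sham replicate 6). That list passed as lower without MI replicate 3 (adjusted p = 0.000471) or Sham replicate 8 (0.0248). Myh2 and Myh1, the type IIA and IIX chains, had log2 fold changes of -0.13 ± 0.20 and -0.23 ± 0.29, and the calcium pump Atp2a1 -0.26 ± 0.19 (-0.11 without Sham replicate 6). The sign for Myh2 turned without MI replicate 1 and that for Myh1 without Sham replicate 6. Myh4, the type IIB chain, was at 1188 ± 1740 against 963 ± 957 CPM, with single MI libraries at 11.4 and 3700 CPM, and its sign depended on the setting.

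**Figure D3:**
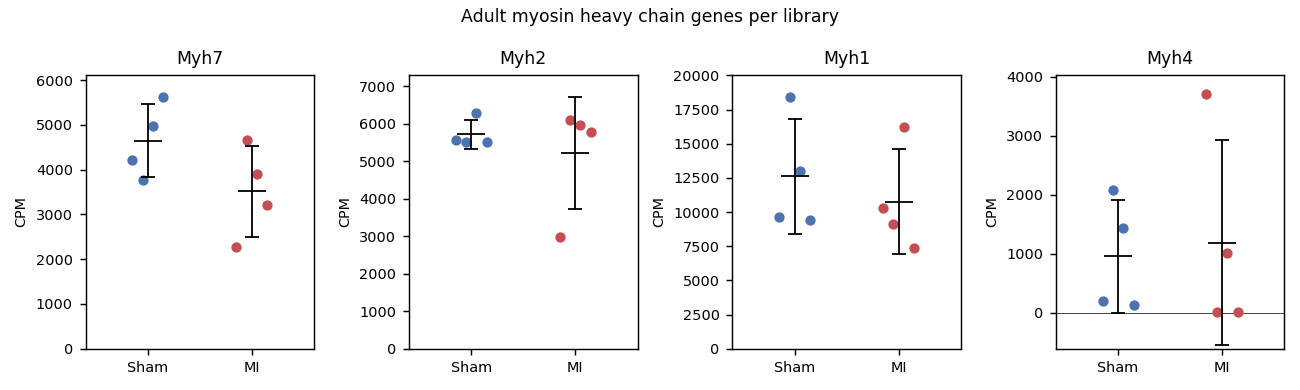
CPM (vertical axes) of the adult myosin heavy chain genes Myh7, Myh2, Myh1 and Myh4, 1 point per library, with a line and bars for the mean ± SD of the 4 Sham and the 4 MI animals. Myh7 averages 3514 in MI and 4645 in Sham with overlapping values, Myh4 spans 11.4 to 3700 CPM within MI, and none of these genes passed the edgeR test.

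Atrophy genes and ubiquitin ligases had 16 of 24 members below 0 and a median log2 fold change of -0.079 (camera adjusted p = 0.297). Trim63 was the 1 member that passed when adjusted over the list alone in edgeR (adjusted p = 0.00107), with 0 over all genes, while DESeq2 called it over all genes (1.36e-05). Usp2, a deubiquitinase, had a log2 fold change of -0.40 ± 0.14, Ddit4, a stress-induced inhibitor of mTOR signalling, -1.02 ± 0.48 (-0.47 without Sham replicate 7), and Cblb, a ubiquitin ligase, -0.18 ± 0.09. Fbxo32, the ligase also called atrogin-1, was at 107.6 ± 7.41 against 102.8 ± 14.5 CPM (0.06 ± 0.10), with a sign that turned without Sham replicate 8. The mean level of the list was 5.52 ± 0.050 log2 CPM in MI against 5.64 ± 0.082 in Sham, an exact permutation p of 0.0286 before adjustment, the smallest that 70 arrangements allow, and 0.324 after adjustment over the lists. Autophagy and lysosome genes had a median of 0.0066 and a mean of -0.030 over 26 members (camera adjusted p = 0.955), with Bnip3 at 0.26 ± 0.11 and Atg7 at -0.33 ± 0.15.

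Metabolic lists other than oxidative phosphorylation did not pass. Tricarboxylic acid cycle enzymes had 13 of 17 members above 0 and a median log2 fold change of 0.079 (camera adjusted p = 0.0875), led by Fh at 0.20 ± 0.07 and Suclg1 at 0.15 ± 0.07, and passed as higher without MI replicate 1 (0.0104). Fatty acid uptake and oxidation had a median of 0.014 and a mean of -0.032 over 31 members (0.805), with the fatty acid carrier Fabp3 at 0.28 ± 0.13, and passed as higher without MI replicate 1 (0.0253). Glycolysis and glycogen genes had a median of -0.040 over 27 members (0.567), with Pfkfb3, an activator of glycolysis, at 0.82 ± 0.20 and the insulin-responsive glucose carrier Slc2a4 at -0.23 ± 0.08, and passed as lower without Sham replicate 8 (0.0418). The mitochondrial regulator Ppargc1a was at 58.3 ± 4.60 against 60.5 ± 9.22 CPM (SD, n = 4 each), a log2 fold change of -0.05 ± 0.11 whose sign turned without Sham replicate 8.

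Genes of reactive oxygen species and antioxidant defence had 20 of 32 members above 0 and a median log2 fold change of 0.076. The list did not pass with camera (adjusted p = 0.0661), and the adjusted p was 0.327 with an estimated correlation and 0.355 with fry. The superoxide dismutase Sod1 was at 0.28 ± 0.09, the peroxiredoxins Prdx3 and Prdx1 at 0.21 ± 0.08 and 0.28 ± 0.10 (the latter 0.18 without MI replicate 1), and thioredoxin, Txn1, at 0.26 ± 0.10. Cybb, a catalytic subunit of NADPH oxidase, was at 7.43 ± 1.88 against 8.83 ± 6.25 CPM (-0.32 ± 0.43), and its sign turned without Sham replicate 7. The list passed as higher without MI replicate 2 (0.0395), Sham replicate 7 (0.0213) or Sham replicate 8 (0.0369), and with the animal number range as a term (0.0224). Unfolded protein and heat shock genes had a median of -0.039 over 26 members (0.890), with the small heat shock protein gene Cryab at 0.29 ± 0.09 and Hsp90b1 at -0.20 ± 0.08. Genes of calcium release and excitation-contraction coupling had a median of 0.00084 over 22 members while camera leaned lower (0.858), with Cacna1s, the pore subunit of the muscle calcium channel, at -0.24 ± 0.13 (-0.15 without MI replicate 4).

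Extracellular matrix genes were divided, with 15 of 31 members above 0 and a median log2 fold change of -0.0046 (camera adjusted p = 0.786). Elastin, Eln, was at 13.1 against 22.4 CPM (-0.78 ± 0.26), the elastin crosslinker Loxl1 at -1.01 ± 0.36 (-0.61 without Sham replicate 8) and the membrane-bound protease Mmp14 at -0.57 ± 0.20, while the proteoglycan gene Lum was at 273.9 against 161.5 CPM (0.76 ± 0.26). The collagen genes Col1a1 (0.14 ± 0.40) and Col3a1 (-0.0046 ± 0.26) differed by less than the spread between animals, and their signs depended on the setting, that of Col3a1 also on the scaling. Without MI replicate 4 the list passed as lower (0.0002). Fibroblast and fibro-adipogenic progenitor markers, which share Lum, had 9 of 15 members above 0 and a median of 0.016 (0.547), with Fap at 0.47 ± 0.16, Dcn at 0.34 ± 0.15 (0.20 without MI replicate 4) and Smoc2 at -0.25 ± 0.13 (-0.14 without Sham replicate 8). Tendon markers had a median of 0.0034 over 9 members while camera leaned lower (0.822), with Scx at -0.18 ± 0.22 (-0.06 without Sham replicate 5) and Tnmd at 0.98 ± 1.34, a sign that turned without MI replicate 4 and with limma-voom.

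Immune lists did not pass. Cytokines, chemokines and their signalling genes had 21 of 30 members below 0 and a median log2 fold change of -0.098 (camera adjusted p = 0.463), with the interleukin receptor gene Il6r at -0.73 ± 0.21 and Cxcl12 at 0.38 ± 0.16 (0.24 without MI replicate 4). Macrophage and monocyte markers had 13 of 19 members below 0 and a median of -0.13 (0.567), with the scavenger receptor Cd163 at -0.75 ± 0.31 and the complement gene C1qa at -0.71 ± 0.36. Without Sham replicate 7 these values were -0.34 and -0.22, and the list turned to higher in MI (0.0342). Lymphocyte markers had 6 of 6 members below 0 and a median of -0.34 (0.567), with Klrd1 at -0.87 ± 0.61 and Cd4 at -0.33 ± 0.24. These rested on Sham replicate 7, where the mean level of the list was 2.05 log2 CPM against at most 0.552 in the other Sham libraries. Without it Klrd1 was at -0.09 and Cd4 at -0.07. Neutrophil and mast cell markers had a median of -0.095 over 7 members (0.547), with the mast cell tryptases Tpsb2 and Tpsab1 at -0.65 ± 0.29 and -0.37 ± 0.26, or -0.39 and -0.14 without Sham replicate 7. The neutrophil gene S100a9 was at 0.94 ± 0.66, or 0.04 without MI replicate 4, and the chymase Cma1 at -0.16 ± 0.22, a sign that turned without MI replicate 3. Interferon-stimulated genes had 18 of 24 members above 0 and a median of 0.085 (0.217), with the RNA sensor Ddx58 at 1.13 ± 0.43 and Irf9 at 0.25 ± 0.12. That list passed as higher without MI replicate 2 (0.00438), without Sham replicate 6 (0.0298) and with the animal number range as a term (0.00485).

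Vascular lists did not pass either. Endothelial markers had 11 of 19 members below 0 and a median log2 fold change of -0.032 (camera adjusted p = 0.492), and passed as lower without MI replicate 2 (0.0243). Lyve1, a marker of lymphatic endothelium, was at 53.0 against 90.0 CPM (-0.76 ± 0.25), the water channel Aqp1 at -0.35 ± 0.13 (-0.23 without Sham replicate 7) and Egfl7 at -0.31 ± 0.15 (-0.20 without MI replicate 1), while the endothelial gene Emcn lay in the other direction at 0.30 ± 0.12 (0.19 without MI replicate 4). Smooth muscle and pericyte markers had 10 of 16 members below 0 and a median of -0.066 (0.688). Rgs5 was at 0.43 ± 0.14 and Abcc9 at 0.17 ± 0.09 (0.09 without MI replicate 4), while Cspg4 was at -0.28 ± 0.17 (-0.14 without Sham replicate 8) and Cnn1 at -0.64 ± 0.39, or -0.16 without Sham replicate 7. Angiogenesis and hypoxia genes had a median of -0.022 over 20 members while camera leaned higher (0.955), with adrenomedullin, Adm, at -0.39 ± 0.14 and Epas1 at -0.48 ± 0.22 (-0.30 without MI replicate 1).

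Regeneration and denervation genes had 14 of 22 members below 0 and a median log2 fold change of -0.12 (camera adjusted p = 0.567). Igf2, a growth factor of developing muscle, was at -0.48 ± 0.13 and Igf1 at 0.46 ± 0.18. Chrng, the fetal subunit of the acetylcholine receptor, was at 1.65 against 0.929 CPM (0.91 ± 0.34). Runx1 was at 0.586 against 0.936 CPM (-0.69 ± 0.30), and both genes lay close to the counting floor of the smallest libraries. Immediate early genes, which are induced within minutes by handling, had 15 of 19 members below 0 and a median of -0.24 (0.0875), with Zfp36 at -0.49 ± 0.19, Nr4a1 at -0.45 ± 0.18 and Myc at -0.51 ± 0.33. Without Sham replicate 6 Nr4a1 was at -0.29 and Myc at -0.23. Their member Atf3 was at 266.7 CPM in Sham replicate 6 and at most 16.4 in the other libraries, and its log2 fold change of -2.75 ± 1.2 became -0.16 without that library. The immediate early list passed as lower without Sham replicate 5 (0.000782) or Sham replicate 8 (0.0369). Circadian clock genes had a median of -0.13 over 14 members (0.774), with the core clock gene Arntl at -0.73 ± 0.26 and Cry2 at -0.36 ± 0.18 (-0.23 without MI replicate 1).

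Markers of other tissues that a diaphragm sample can hold gave no call. Adipocyte markers had a median log2 fold change of 0.084 over 19 members (camera adjusted p = 0.779), with Pparg at 0.45 ± 0.19 (0.29 without MI replicate 4) and Fasn at -0.73 ± 0.39, or -0.27 without Sham replicate 7. Mesothelial markers had 9 of 11 members below 0 and a median of -0.14 (0.492), with C3 at -0.58 ± 0.55 and Msln at -0.47 ± 0.48, and passed as lower without MI replicate 1 (0.0349) or MI replicate 4 (0.0133). Msln was at -0.13 without Sham replicate 8 and C3 at -0.30 without MI replicate 2. Krt18 was at 0.55 ± 0.75, or 0.02 without MI replicate 4, with a sign that turned with 1 surrogate variable as a term. Slpi was at -0.54 ± 1.06, with a sign that turned without Sham replicate 7. Liver markers had a median of 0.28 over 5 members (0.955), with Tf at -0.64 ± 0.35 (-0.42 without MI replicate 1) and Fgg at 1.05 ± 0.74. The value of Fgg was 0.09 without MI replicate 4 and 0.08 with 1 surrogate variable as a term. Cardiac muscle markers had 6 of 9 members above 0 and a median of 0.34 (0.5), with the cardiac myosin gene Myh6 at 1.40 ± 0.99. Ryr2 was at 0.41 ± 0.32 (0.25 without MI replicate 2) and Gja1 at -0.29 ± 0.24 (-0.15 without MI replicate 2). Gata4 was at 0.34 ± 0.28, or 0.06 without MI replicate 4. Keratinocyte and epithelial markers had 2 tested members, Perp at 0.19 ± 0.54 and Krt10 at 0.03 ± 0.18, too few for a test, and both signs depended on the setting. In the lists other than the red blood cell, Schwann cell and atrophy lists, 0 members passed in edgeR over all genes and 0 when adjusted over the list alone. Of the members of these other lists, DESeq2 called only Cox5a over all genes.

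The mean levels of the lists per library gave 0 differences past the threshold after adjustment. With 34 lists and 70 arrangements at least 20 lists would have had to tie at the smallest exact p for any to pass, so this count says little about the levels. The red blood cell and oxidative phosphorylation lists, like the atrophy list, reached the smallest exact permutation p of 0.0286 (two-sided), which adjusted to 0.324 over the lists. Oxidative phosphorylation genes averaged 8.81 ± 0.045 log2 CPM in MI and 8.66 ± 0.080 in Sham (SD, n = 4 each). The lowest MI library, at 8.770, barely exceeded the highest Sham library, at 8.767.

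The groups did not separate along the main axes of variation. Over the 500 most variable genes, component 1 held 24.7% of the variance, of which 0.947% lay between MI and Sham (exact permutation p = 0.771, two-sided). Component 2 held 21.4%, of which 2.21% lay between the groups (exact permutation p = 0.629). Over all tested genes the shares between groups were 19.6% and 0.669% (exact permutation p = 0.314 for component 1).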

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

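The rule for libraries standing apart was set beforehand, and its use on list members was added after the values of the lists and leading genes had been seen. It was applied to 296 groups of 4 values, the levels of each gene and list named above in MI and in Sham, and picked out 20 in which the highest or lowest library lay far from the other 3. Chance picks out about 1 in 20 such groups. No explanation was tested for these values.

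Among list levels, MI replicate 1 was lowest for tricarboxylic acid cycle genes, at 9.705 log2 CPM with the nearest MI library at 9.831, and for Schwann cell and nerve markers, at 2.487 with the nearest at 2.602. Among muscle genes, Myh2 was at 2980 CPM in MI replicate 1 with the nearest MI library at 5772, and at 6292 in Sham replicate 7 with the nearest at 5552. Trim63 was at 358.6 CPM in Sham replicate 6 with the nearest Sham library at 323.1, so the library that stood apart lay farther from MI. Ppargc1a was at 65.13 CPM in MI replicate 4 (nearest 56.85).

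Sham replicate 8 was highest for Casp12, at 4.921 CPM (nearest 3.511), for Col3a1, at 545.1 (366.5), and for Hsp90b1, at 316.7 (307.2). It was also highest for the fibroblast gene Smoc2, at 31.86 (23.88), and for the mesothelial gene Krt18, at 9.842 (3.742). Rps13 was at 37.42 CPM in MI replicate 2 (nearest 46.14), and the endothelial gene Egfl7 at 17.9 in MI replicate 1 (nearest 25.36). The stress-induced transcription factor gene Atf3 stood out most, at 266.7 CPM in Sham replicate 6 against 16.36 in the nearest Sham library.

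Sham replicate 7, the library with the most counts, gave 7 of the 20 values. It was highest for the macrophage complement gene C1qa, at 32.79 CPM (nearest 14.03), for the natural killer cell gene Klrd1, at 2.469 (0.8054), for Epas1, at 126.5 (107.9), and for Slpi, at 26.7 (4.906), besides Myh2 above. It was lowest for Cxcl12, at 156.3 CPM (193.5), and Psma2, at 104.7 (113.9).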

How the results depend on the processing

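Thinning to equal depth was the only alternative chosen after seeing the data. With a prior count of 0.5 in place of 2, the number of lists whose mean levels passed the exact permutation test was unchanged. The edgeR count of 0 higher and 0 lower genes held under each alternative except DESeq2, which called 9 higher and 5 lower, and leaving out MI replicate 1 (Alas2) or MI replicate 3 (Zp2, chosen after its value was seen), which gave 0 to 1 higher over the 8 left-out libraries. Besides genes named in the report, DESeq2 called Hbb and Mical2, named here after their values were seen. The causes were not tested. Lists higher by camera were 0 with an estimated correlation and 0 with fry, and 4 to 7 over left-out libraries, where lists lower were 0 to 3. For the red blood cell, oxidative phosphorylation, ribosomal, proteasome and Schwann cell lists, the adjusted p was 0.1507, 0.7119, 0.9656, 0.9656 and 0.327 with an estimated correlation and 0.2551, 0.2775, 0.667, 0.5783 and 0.3293 with fry. The estimated correlations were 0.58, 0.414, 0.57, 0.431 and 0.0134 in place of the preset 0.01. That for the Schwann cell list is close to the preset, yet its unadjusted camera p went from 0.00405 to 0.0297. The correlation alone therefore does not account for its lost call, and may not for the others. What else differs between the forms of camera, and why the calls were lost with fry, was not tested. Over left-out libraries the Schwann cell list ranged from 0.006682 to 0.09236, and the other 4 calls held. Macrophage markers turned from lower to higher without Sham replicate 7, at adjusted p = 0.03422 in a range of 0.03422 to 0.6872 over left-out libraries, and the cause was not tested. Other lists passed in the direction already measured in 18 cases. Of the 113 genes named in the text under the rule, 56 had a log2 fold change that moved by over 1.5 times without 1 library. The sign was kept in each of up to 19 alternatives by 99, among them the genes picked for no overlap between groups. The other 14 are given with their sign changes in the report. No paired analysis was possible because the individual numbers 1 to 8 are not shared between groups. A gene under 0.378 CPM has fewer than 3 counts in the smallest library. In the simulation 1.5-fold changes were recovered in 32.8% of cases. That rate holds with 200 genes changed and is not a detection limit for data in which few or no genes pass.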

Other observations

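The lists of lymphatic and glucocorticoid-responsive genes, the test of the shared library axis, the splits for DESeq2, for unadjusted p and for lists, and the test of the genes with 2 levels were set before their results were seen; the tests of globin copies, whole blood, depth and mitochondria, the splits for edgeR, and the intervals over animals and left-out medians of the gene sets were chosen after. A few genes, chosen after their values were seen, had 2 separate levels among the 8 animals, with a gap of at least 2 on the log2 scale and an upper level of at least 5 CPM. Fam111a, a gene of DNA replication and antiviral defence, was at 68.2 to 105.7 CPM in MI replicates 1 and 4 and Sham replicates 5 and 8, and at 1.09 to 2.88 CPM in the other 4 libraries. The mitochondrial ribosomal protein gene Mrpl43 was at 31.5 to 64.8 CPM in MI replicate 1 and Sham replicates 5, 7 and 8, and at 4.06 to 5.42 elsewhere. Mrps10, of the same organelle ribosome, was at 22.9 to 24.2 CPM in MI replicates 1 and 2 and Sham replicate 8, and at 3.69 to 4.89 elsewhere. RT1-Bb, a class II histocompatibility gene, and Magea11 also had 2 levels. The 5 genes divided the animals in 5 distinct ways and 0 of them divided MI from Sham.

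A source of 1 batch or 1 contaminating tissue shared by some libraries would divide the animals in 1 way for most of these genes. The most common way held 20% of them, which argues against 1 such source for the levels of these genes. Only genes with a gap of at least 2 on the log2 scale were counted, so a batch of smaller shifts could not appear here. Simulated libraries with no such structure gave at most 2 genes in each of 20 draws. Inherited variants of the outbred Sprague-Dawley strain, acting on expression or on mapping to the reference, may account for the 2 levels and stay open, since the counts hold no genotype.

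Other splits of the 8 animals into 4 and 4 were counted, 35 with the real one. Since the real split gave 0 edgeR calls, all 35 of 35 reach that count whatever the data (highest other 2), and this count decides nothing. With DESeq2 13 of 35 gave at least the 14 calls of the real split (highest other 59), so chance cannot be excluded. The split with 59 set MI replicates 1 and 4 and Sham replicates 5 and 8 against the rest, which is also how Fam111a divides them. So many calls may point to a structure of the animals other than the surgery, but this was not tested. In that split edgeR called 1 gene, and 1041 genes had an unadjusted p under 0.05. For genes at an unadjusted p under 0.05, 4 of 35 splits gave at least the 856 of the real split (highest other 1201), and chance cannot be excluded. For camera lists with the preset correlation, 35 of 35 splits gave at least the 5 of the real split (highest other 17). No split gave fewer than 5 lists, so a preset-correlation call in these libraries does not by itself set the surgery apart from an arbitrary division of the animals.

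Red blood cell genes were higher in MI by a median of 1.10 on the log2 scale. Reads shared between globin copies do not account for it alone, because Alas2 and Slc4a1, which have no near-identical copy, were also higher, with the lower of their 95% lower bounds at 0.456. Whole blood left in the tissue would also raise S100a9, an abundant neutrophil gene, whose log2 fold change was 0.936 with a 95% interval of -0.675 to 2.55, too wide to decide, and which was 0.0358 without MI replicate 4, so 1 library carries it. S100a9 was the 1 member above 0 among 7 tested neutrophil and mast cell markers. All 6 tested lymphocyte markers lay below 0, a lean that rested on Sham replicate 7, so white cell markers do not decide this either. More retained or circulating red cells in the MI animals may explain the higher red blood cell genes. Blood left at dissection cannot be told apart from a change in the animals.

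Oxidative phosphorylation, ribosomal protein and proteasome genes were each slightly higher in MI. After thinning to equal depth the oxidative phosphorylation median was 0.168 against 0.173 before. Thinning keeps each gene's expected share of its library, so the median of these abundant genes had little room to move. It therefore does not decide whether unequal depth plays a part. More mitochondria as the whole cause cannot be told apart from a change in the respiratory genes alone. The 34 other mitochondrial enzymes tested had a median of 0.0570 (bootstrap SE over genes 0.022), below the 0.173 of the respiratory list, but that spread leaves out the animals. The gap between the mean levels of these sets was larger in MI by 0.107, with a 95% interval over animals of -0.070 to 0.283, and without MI replicate 1 the medians were 0.103 and 0.132. An axis along which libraries differ in all these lists, as RNA quality could give, cannot be told apart from the surgery: with the ribosomal level as a term the oxidative phosphorylation difference was 0.106 (95% interval -0.017 to 0.229) against 0.150 without it. The interval then holds both 0 and the full difference.

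Hypotheses for the genes with the smallest p were tested on lists written before the results of those lists were seen. The leading genes were picked from these same libraries, so other genes that vary with them across animals could lean the same way. The p-values of these lists are not adjusted, and the lists were not tested over other splits of the animals. Fewer lymphatic vessels in MI could lower Flt4 and Figf together, and 8 of the 8 tested of 16 other lymphatic markers lay below 0. Their median of -0.13 (bootstrap SE 0.107) lay above the -0.5 that a loss of this size called for, by more than the bound set beforehand. That bound left out the spread between animals: the mean level of the list differed by -0.346 with a 95% interval of -0.863 to 0.172, and without MI replicate 1 the median was -0.447. The explanation therefore cannot be told apart from lower expression of Flt4 and Figf alone. Prox1, another lymphatic marker kept out of that list, was at -0.014 ± 0.15, and Lyve1 at -0.76 ± 0.25. The camera p of the list was 0.0660, and 0.125 with an estimated correlation, and the exact permutation p of its mean level was 0.2. Less glucocorticoid signalling in MI could lower Trim63 and Zbtb16, both glucocorticoid-responsive. Of 19 other such genes, 7 of them also in the fixed lists, 16 lay below 0, with a median of -0.16 (bootstrap SE 0.059). The 4 with an unadjusted p under 0.05, named after their values were seen, were Fkbp5 at -1.03 ± 0.32, Tsc22d3 at -0.39 ± 0.16, Fam107a at -0.38 ± 0.15 and Map3k6 at -0.87 ± 0.32. The camera p was 0.0018, 0.0421 with an estimated correlation, and the exact permutation p of the mean level was 0.0857. That level differed by -0.260 with a 95% interval over animals of -0.517 to -0.0019. Over left-out libraries the median ranged from -0.254 without Sham replicate 6 to -0.0974 without Sham replicate 7. The hypothesis stays open and was neither met nor excluded by its own bound of -0.25. Corticosterone, time of day and handling before collection are not given in the sources used here.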
